A study of Mus musculus with 20 samples.

How the data were processed

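The series holds 20 libraries from the external genitalia of ICR mouse embryos at E16.5: AR (2, male), H3K27Ac and H3K4me1 (2 per sex each), Sp1 (1 per sex) and 8 input libraries, which were not analysed here. Per the labels' protocols, pooled genitalia were crosslinked with EGS and formaldehyde, chromatin was cut with MNase and by sonication, and libraries were prepared and sequenced on the Ion Proton and NextSeq 500 platforms. The labels do not tie a platform to a library. Each library came from a pool of genitalia, and the series' design calls the replicates biological and independent.

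Per the submitters' processing notes, FastQC 0.11.5, Bowtie2 2.3.2 and SAMtools 1.5 are listed with genome build mm10. The authors deposited 1 peak list for each library other than the inputs and named MACS as the caller for most of them. Its version and its settings are not given in the sources used here. The sample titles name an input for each AR library and for each mark library of replicate 1. They name the remaining inputs by sex and replicate number only. Which input the caller set against each list is not given. Of the 12 deposited peak lists, those of AR and of replicate 1 of each mark are 5-column BED files, whose deposited score is a −log10 value, and those of replicate 2 and of Sp1 are narrowPeak files, with a deposited integer score, a fold enrichment (a ratio) and −log10 p and q values as the authors' caller gave them. The lowest score in every list lies between 1.30 and 1.45 on the −log10 scale. The shortest peak is 200 bp in each BED list and 300 bp in each narrowPeak list, so the 2 kinds of list differ in their least width. The 5-column lists do not name their score, which was read as −log10 q from its lowest value. The authors' scores were used only to rank peaks within a list or to filter a list. The files give no read counts, so depth per library is unknown, and a list's number of peaks depends on it.

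Peaks on chromosomes 1 to 19, X and Y were kept. Lists were merged into a union of regions, joining peaks that overlap by 1 bp or more, and a region counted as called in a library when a peak of that library overlapped it. Shared AR regions were those with a peak of both AR lists. Marks were taken as present in a sex when called in both replicates. Overlap with chance was tested by shifting the query list by a random distance around each chromosome's span, 1000 times (100 times for the alternatives and for regions called in a single AR replicate), with a one-sided permutation p. The smallest p these give is 0.001 and 0.0099. Shares carry 95% Wilson intervals. Associations were tested with two-sided Fisher's exact tests, and 0.5 was added to each cell for odds ratios. Regions near each other are not independent, and p-values over regions do not measure the spread between animals.

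Genes came from a RefSeq table of GRCm38.p6, the same build as mm10, with 21883 protein-coding genes on these chromosomes. It gives the start and end of each gene but neither strand nor exons. The planned windows around transcription start sites were therefore placed around both gene ends (1 kb to either side for marks, 50 kb for AR), and introns were not told from exons. No genome sequence was used here, so the planned motif counts were not made. The 18 gene lists were fixed before the data were examined, with Benjamini-Hochberg adjustment over the lists. Genes named in the text follow a rule fixed at the same time: list genes with shared AR within 50 kb, with Mafb and Ar in any case; the 10 best shared AR regions by the worse of their ranks, and the 10 best with male Sp1; the 10 best-ranked genes and regions of each sex-specific set; list members marked in one sex only; and the 10 longest H3K27Ac domains. A region is named by the protein-coding gene nearest to it.

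Sex-specific regions were those called in both libraries of one sex and neither of the other, and were set beside the other 2 splits of the 4 libraries. The alternatives were a stricter overlap (50% of the shorter interval), the better-scoring 50% of each list, equal list lengths, autosomes only, a merge gap of 500 bp, other windows (5, 10 and 100 kb), a domain gap of 5 kb, and leaving out each replicate. Alternatives added after seeing the data were a background of genes with H3K27Ac, Hox genes left out, gene spans extended by 50 kb, equal AR list length, female in place of male Sp1, per-replicate exact McNemar tests, and Mantel-Haenszel odds ratios with the replicate number as a block.

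The procedures were tested on simulated data. Lists of the AR sizes placed at random gave a permutation p under 0.05 in 5 of 100 runs. Of the planted regions, 300 of 300 shared and 300 of 300 male-only regions were recovered. The planted intervals were identical in the lists that held them, so full recovery was fixed by design and checks the code only. Random flags at 5% of genes gave any call among the 18 lists in 2 of 100 runs. These flags were drawn gene by gene, whereas neighbouring genes can share an AR region, so this rate may not hold for the AR lists. The patterning list, when raised to 50%, was called in 100 of 100 runs. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.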

Results

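Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the androgen receptor (AR), the GC-box binding transcription factor Sp1 and 2 histone marks in the external genitalia of ICR mouse embryos at E16.5. H3K27Ac marks active promoters and enhancers, and H3K4me1 marks enhancers in general. AR is the nuclear receptor through which testosterone and dihydrotestosterone masculinise this tissue. AR was profiled in males in 2 replicates, each histone mark in 2 replicates per sex, and Sp1 in 1 library per sex. The deposited data were 12 lists of called peaks. The AR lists held 9317 and 3573 peaks, the H3K27Ac lists 46292 to 81740, the H3K4me1 lists 91928 to 121670, and the Sp1 lists 42573 in the male and 29777 in the female. Read depth was not given in the sources used here, so the number of called peaks stands as the only measure of yield, and intervals on shares cover counting error only.

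The first question was where AR bound in the male genitalia. The 618 regions called in both AR replicates included well-known androgen and glucocorticoid responsive genes. Zbtb16, which encodes the zinc finger repressor PLZF, held 8 shared regions within its 184 kb (chromosome 9, 48651797 to 48836225, mm10), and the best-ranked of all shared regions lay inside it (48740016 to 48740648; rank 11 in replicate 1 and rank 7 in replicate 2). Several of the 8 regions lay side by side, from 48736778 to 48740648, and AR regions were not joined across gaps. Fkbp5, which encodes a co-chaperone of steroid receptors, had 5 shared regions, 2 of them inside the gene and 3 beyond one end towards Armc12. The strongest of these (chromosome 17, 28517530 to 28519609) was the top peak of AR replicate 2, with a −log10 score of 60.4, and ranked 22 in replicate 1. Per1, a circadian clock gene, and Klf9, a Krüppel-like factor, had shared regions inside the gene (chromosome 11, 69096656 to 69099883) and 5276 bp outside it (chromosome 19, 23134572 to 23135949).

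The other top-ranked shared regions lay in Isl1, the LIM-homeodomain gene of the genital and limb mesenchyme (chromosome 13, 116302484 to 116303707), in Med9, a Mediator subunit (chromosome 11, 59960502 to 59960940), in Lox, the collagen crosslinking enzyme lysyl oxidase (chromosome 18, 52528666 to 52529570), in Hoxc11 (chromosome 15, 102954467 to 102955254), in Scfd2 (chromosome 5, 74249524 to 74250748), in the predicted gene Gm46866 (chromosome 4, 107435021 to 107436009) and 30358 bp from Dnajc11 (chromosome 4, 151902416 to 151903361). Mafb, a basic leucine zipper gene of the AP-1 superfamily with a known role in male urethral formation, held a shared region within the gene (chromosome 2, 160365918 to 160366676). It scored 6.27 on the −log10 scale in replicate 2 and 1.84 in replicate 1, where it ranked 8436 of 9317. The Ar gene itself (chromosome X, 98148757 to 98323218) carried an AR peak in replicate 2 only (98149866 to 98150123), and H3K27Ac in all 4 libraries.

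The AR replicates shared few peaks, though far more than chance gave. Of the replicate 2 peaks, 622 (17.4%, 95% Wilson interval 16.2 to 18.7) overlapped a replicate 1 peak, against a mean of 8.35 and a maximum of 18 when the list was shifted at random along each chromosome (74.5 times the mean; one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). The shared regions made up 5.04% of the 12263 regions of the union. Among the 100 best peaks of replicate 2, 54 were found in replicate 1, so the better peaks were shared more often. Restricting each list to its better-scoring 50% left 241 shared regions, and taking as many of the best replicate 1 peaks as replicate 2 held left 345.

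AR regions lay in active chromatin that also held Sp1. Of the 618 shared AR regions, 481 (77.8%, interval 74.4 to 80.9) overlapped a male H3K27Ac region called in both replicates, 289 (46.8%, interval 42.9 to 50.7) a male H3K4me1 region and 351 (56.8%, interval 52.9 to 60.7) a male Sp1 peak. Random shifts gave means of 2.08%, 1.95% and 1.87% (permutation test, p = 0.001 for each, the smallest 1000 shifts can give). At 254 regions both marks were present, at 227 H3K27Ac alone, at 35 H3K4me1 alone, and only 24 regions had no peak of either mark in any male library. H3K27Ac and Sp1 met at 340 regions. The 10 best shared regions that also held male Sp1 were the one nearest to Armc12, beyond the end of Fkbp5, and those at Lox, Hoxc11, Per1, Gm46866, Zfp503 (chromosome 14, 21984789 to 21986199), Prickle1, a planar cell polarity gene (chromosome 15, 93595063 to 93595636), and Klf9, with 2 at Isl1.

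Within the 26139 male H3K27Ac regions, those with AR held Sp1 more often than those without. Sp1 was present in 81.1% of 440 regions with AR and in 50.1% of 25699 regions without (odds ratio 4.27, two-sided Fisher's exact test, p = 6.94e-41). The same regions held the female Sp1 peaks in 78.4% and 46.4% of cases (odds ratio 4.17, Fisher's exact test, p = 5.06e-42), so the overlap was not limited to the male Sp1 library. The width of the H3K27Ac regions was not controlled, and a wider region offers more sequence for both AR and Sp1. Male H3K4me1 was also more frequent in the regions with AR (65.9% against 45.7%). Regions called in a single AR replicate had lower shares: 46.7% of those in replicate 2 only and 28.5% of those in replicate 1 only overlapped male H3K27Ac. With the whole list of either replicate in place of the shared regions, the share with H3K27Ac was 52.1% for replicate 2 and 31.8% for replicate 1, the share with H3K4me1 37.0% and 20.0%, and the share with Sp1 31.7% and 24.8%. With H3K4me1 replicate 1 alone, and both AR replicates, the share with H3K4me1 was 70.9%.

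**Figure D1:**
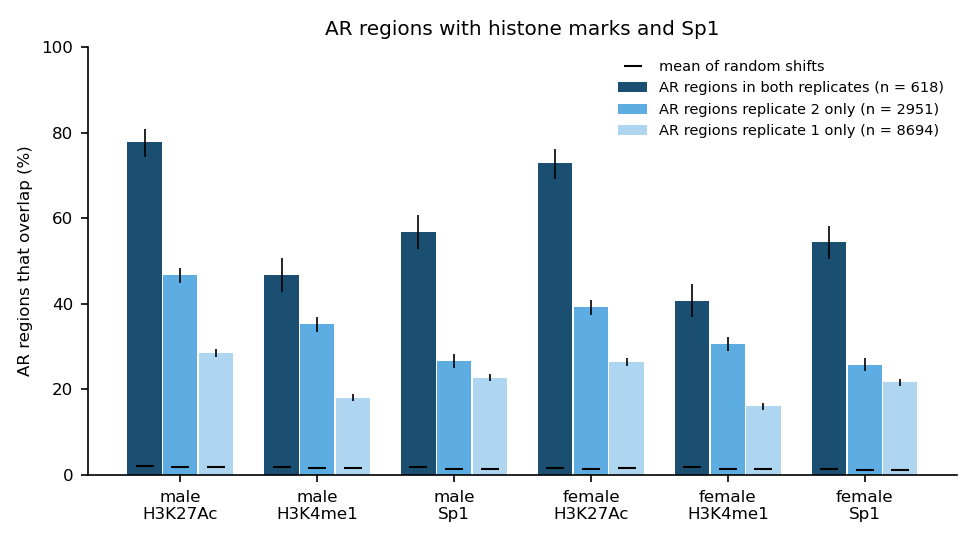
Share of AR regions (y axis, %) that overlapped each histone mark called in both replicates of a sex, or Sp1, for regions called in both AR replicates, in replicate 2 only and in replicate 1 only; error bars are 95% Wilson intervals and black dashes the mean of random shifts. The 618 shared regions stand highest for every mark, with 77.8% in male H3K27Ac.

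AR regions with and without Sp1 had different positions relative to genes. Of the 351 shared AR regions with male Sp1, 61.5% (interval 56.4 to 66.5) lay within 1 kb of an end of a protein-coding gene, against 13.1% (interval 9.58 to 17.7) of the 267 without Sp1, of which 53.6% lay inside a gene and 33.3% between genes. Over all shared AR regions 40.6% were near a gene end, compared with 55.1% of the H3K27Ac regions called in all 4 libraries, 22.6% of the H3K4me1 regions called in all 4 and 58.4% of the Sp1 regions of both sexes. Sp1 regions themselves lay mostly near gene ends, so a split by Sp1 favours such a difference. Other H3K27Ac regions were not split by Sp1, so the difference was not shown to be particular to AR. Gene ends include 3' ends, because the annotation gave neither strand nor exons. With a 5 kb window the share of shared AR regions near a gene end was 57.1%.

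The next question was which developmental programmes lay near AR. Transcription factors that pattern the genitalia and limbs had shared AR regions within 50 kb of a gene end far more often than other genes: 19 of 33, against 4.80% of the other protein-coding genes (Fisher's exact test, adjusted p = 7.79e-16). They were the posterior Hox genes Hoxa13, Hoxd13, Hoxa11, Hoxd11, Hoxd12, Hoxa10 and Hoxd10, the T-box genes Tbx2, Tbx3, Tbx4 and Tbx5, and Isl1, Six1, Twist1, Tfap2a, Mafb, Foxf2, Foxd1 and Meis1. Many of these regions lay at the gene itself. The shared region nearest to an end of Hoxd13 lay inside the gene (chromosome 2, 74668488 to 74669081). It ranked 353 of 3573 in replicate 2 but 6364 of 9317 in replicate 1. Tbx3 held 3 (chromosome 5, the strongest in replicate 1 at 119682536 to 119683504, −log10 score 27.4). Hox and T-box neighbours shared regions. With the Hox genes left out, a choice made after seeing the data, 46.2% of the list had AR nearby (Fisher's exact test, adjusted p = 1.23e-08).

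Androgen pathway genes (7 of 25: Fkbp5, Zbtb16, Sgk1, Klf9, Per1, Mafb and the coactivator Ncoa2; Fisher's exact test, adjusted p = 0.00128) and Hedgehog pathway genes (4 of 12: the receptor genes Ptch1 and Ptch2, the inhibitor Sufu and the co-receptor Gas1; adjusted p = 0.0103) also had AR nearby more often than other genes. So did genes of the mesenchyme and extracellular matrix (5 of 20: the collagen genes Col1a1, Col5a1 and Col6a1 and the mesenchymal transcription factors Prrx1 and Twist2; Fisher's exact test, adjusted p = 0.0103) and of the FGF pathway (4 of 14: Fgfr1 and the feedback inhibitors Spry2, Spry4 and Dusp6; adjusted p = 0.0137). Some nearest regions were weak in 1 replicate. Those of Spry2 and Spry4 ranked 3221 and 3130 of 3573 in replicate 2 (134 and 303 in replicate 1). That of Dusp6 ranked 8517 of 9317 in replicate 1 (1157 in replicate 2). In other lists, Twist1 and Col5a1 ranked 3572 and 3328 in replicate 2 (6 and 360 in replicate 1). Six1 and Tfap2a ranked 3160 and 3501 in replicate 2 (1809 and 1392 in replicate 1). Foxf2 ranked 7406 in replicate 1 (84 in replicate 2). Sufu ranked 4855 in replicate 1 and 3016 in replicate 2. At Ptch1 the region lay inside the gene, 9149 bp from an end (chromosome 13, 63563790 to 63564311). Shh, the ligand of the pathway, had no shared AR region within 50 kb. The Wnt pathway had 4 of 22 (Wnt5a, Axin2, Sfrp2 and Fzd1) and did not pass (Fisher's exact test, adjusted p = 0.0611). All p-values of these lists are from two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 18 lists fixed before the data were examined, so they are adjusted over the lists alone, and they count genes, not animals.

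None of the other lists passed. They contributed Id1 and Smad7 of the BMP and TGF-beta pathway (2 of 18), Tpm1 and Rhob of smooth muscle and cell migration (2 of 12), Tie1 and Erg of endothelium (2 of 10), Rara of the other nuclear receptors (1 of 12), Krt18 of surface and urethral epithelium (1 of 20), Pax3 of skeletal muscle (1 of 11), Sox10 of neurons and Schwann cells (1 of 10), Eef1a1 of the housekeeping genes (1 of 14) and Ins2 of the genes of organs not sampled (1 of 20), with 0 of 10 in cartilage and bone, 0 of 10 in blood and immune cells and 0 of 8 among the coding sex-linked genes. Against only those genes with H3K27Ac at an end in all 4 libraries, chosen as background after seeing the data, the same number of lists, 5, passed. With the replicate 1 list alone only 2 passed, and the adjusted p was 0.552 for the androgen, 0.0645 for the Hedgehog, 0.145 for the mesenchyme and 0.0878 for the FGF list. In Fisher's exact tests the FGF list was also lost with the replicate 2 list alone (adjusted p = 0.512), within 10 kb (adjusted p = 0.0966) and with the nearest gene end only (adjusted p = 0.111).

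**Figure D2:**
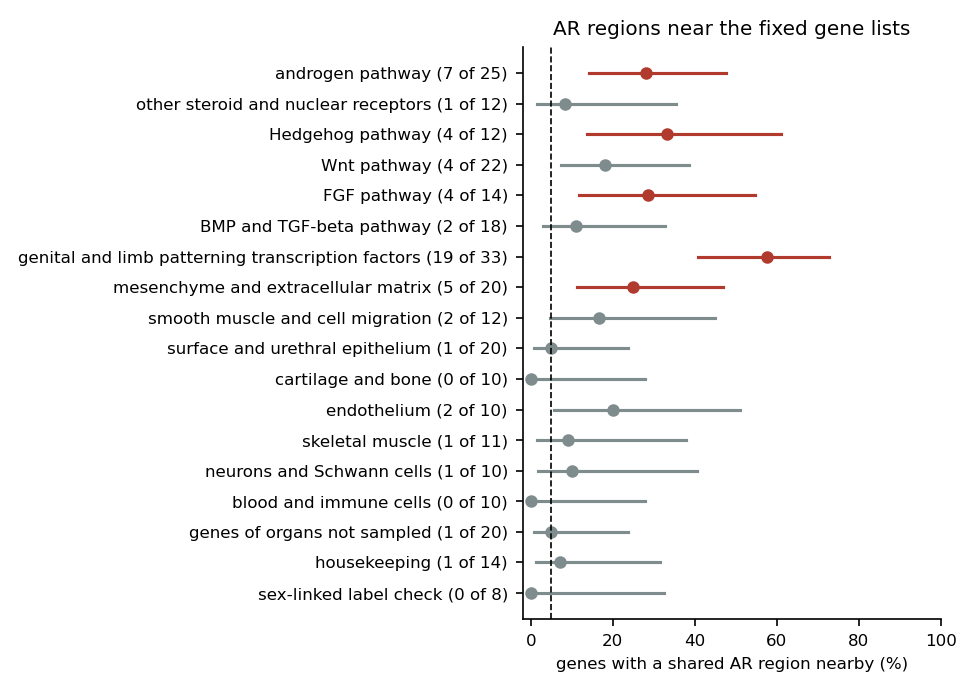
Percentage of the genes of each fixed list (x axis, number of genes in brackets) with a shared AR region within 50 kb of a gene end; lines are 95% Wilson intervals, the dashed line is the share of all protein-coding genes (4.88%), and red marks an adjusted p under 0.05 in Fisher's exact test. Patterning transcription factors stand highest at 57.6%.

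The active mark was frequent at the ends of patterning, signalling and mesenchymal genes and of housekeeping genes, and rare at those of skeletal muscle. H3K27Ac lay within 1 kb of a gene end in all 4 libraries at 10158 of 21883 protein-coding genes (46.4%). It did so at 31 of 33 patterning transcription factors (adjusted p = 1.51e-07), 17 of 20 mesenchyme genes (adjusted p = 0.00455), 11 of 12 Hedgehog genes (adjusted p = 0.00735), 12 of 14 FGF genes and 12 of 14 housekeeping genes (adjusted p = 0.0131 for each), 14 of 18 BMP and TGF-beta genes (adjusted p = 0.0194) and 16 of 22 Wnt genes (adjusted p = 0.0344; Fisher's exact tests). Skeletal muscle genes, which mark a tissue largely outside this structure, had 0 of 11, and genes of organs not sampled 2 of 20, both below other genes (adjusted p = 0.00566 for each, Fisher's exact test). The Hedgehog gene without the mark was Shh, whose gene ends carried H3K4me1 in all 4 libraries and Sp1 in both sexes. The remaining 9 lists did not pass: androgen pathway 16 of 25, other nuclear receptors 5 of 12, smooth muscle 6 of 12, epithelium 7 of 20, sex-linked genes 4 of 8, and cartilage, endothelium, neurons and Schwann cells, and blood 3 of 10 each. With windows of 5 kb only 6 lists passed in Fisher's exact tests, and the FGF list (adjusted p = 0.0630), the housekeeping list (adjusted p = 0.0630) and the Wnt list (adjusted p = 0.0653) were lost.

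Long stretches of H3K27Ac often held AR. Joined across gaps of up to 10 kb, the regions called in all 4 libraries formed 11636 domains, of which 3.34% held a shared AR region; among the 100 with the longest coverage, 43 did, and among the 10 longest, 9 did. The longest (chromosome 7, 142428962 to 142590371) covered 127.3 kb and held the protein-coding genes Syt8, Tnni2, Lsp1, Tnnt3 and Mrpl23. Only protein-coding genes were named in these domains, so other genes inside them are not listed. Others lay over nuclear receptor genes and cofactors: Rxra, the retinoid X receptor (chromosome 2, 27666519 to 27781303), Ncor2, a nuclear receptor corepressor (chromosome 5, 125095190 to 125191036), and Thra and Nr1d1, the thyroid hormone receptor alpha and REV-ERB alpha genes, with Med24 and Msl1 (chromosome 11, 98704787 to 98798216), the only one of the 10 without AR. The domain over Nfix, with Nacc1, Trmt1 and Lyl1 (chromosome 8, 84684983 to 84801503), held 5 shared AR regions. The rest lay over Ahdc1 and Wasf2 (chromosome 4, 133010040 to 133132620), Zmynd8 (chromosome 2, 165816807 to 165915434), and over 3 stretches with no protein-coding gene end inside (chromosome 11, 117251192 to 117357530; chromosome 2, 30635178 to 30726503; chromosome 12, 79877563 to 79995967). Longer domains offer more sequence for overlap, and no test was made of these counts. Joined across gaps of up to 5 kb, 6 of the 10 longest domains lay in those named here, and 8 of the 10 held AR.

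**Figure D3:**
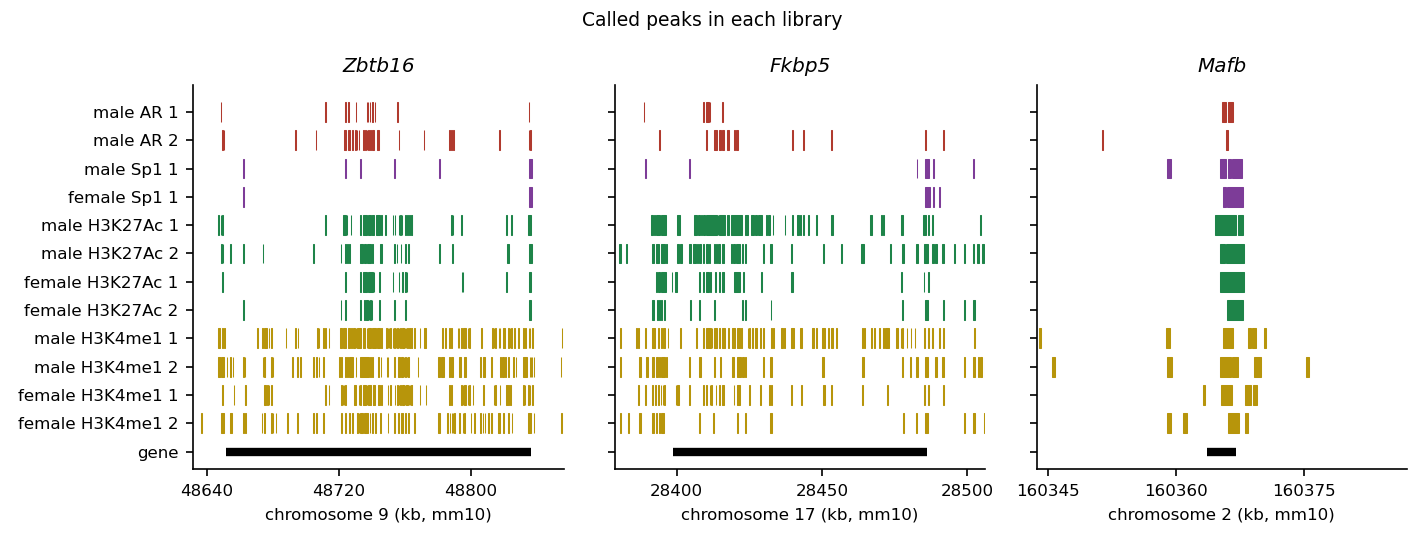
Called peaks in each of the 12 libraries (rows; number after the mark is the replicate) over Zbtb16, Fkbp5 and Mafb with 20 kb on either side (x axis, position in kb, mm10); boxes are peaks, and the black bar is the gene. Zbtb16 shows 8 shared AR regions inside the gene, and Mafb a shared AR region within H3K27Ac and Sp1 peaks of both sexes. The shared AR regions 24508, 29611 and 31380 bp beyond Fkbp5, with the strongest of that gene, lie outside its panel.

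Sp1, a general promoter factor, was compared between the sexes. Of the male Sp1 peaks, 43.3% (interval 42.8 to 43.7) overlapped a female peak, and of the female peaks 62.0% (interval 61.4 to 62.5) overlapped a male peak. Among the 2000 best peaks of each list, 83.0% of the male peaks and 83.0% of the female peaks were shared. The 17592 regions called in both sexes lay in male H3K27Ac in 64.7% of cases, against 15.5% of the 24156 male-only and 21.7% of the 11325 female-only peaks. At gene ends, by Fisher's exact tests, Sp1 in both sexes was more frequent at patterning transcription factors (26 of 33, adjusted p = 0.00691), Hedgehog genes (11 of 12, adjusted p = 0.0105), Wnt genes (18 of 22, adjusted p = 0.0105) and BMP and TGF-beta genes (14 of 18, adjusted p = 0.0485) than at other genes (48.1%). It was less frequent at skeletal muscle genes (0 of 11, adjusted p = 0.00944) and genes of organs not sampled (3 of 20, adjusted p = 0.0105; Fisher's exact tests), and the other 12 lists did not pass. With 1 library per sex the difference between the sexes has no replicate check, and at equal list length 55.0% of the male peaks were shared.

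Marks at sex-linked genes followed the sex given in the labels. Xist, the RNA that silences the inactive X chromosome, carried H3K27Ac at a gene end in both female and neither male library. The Y-linked Uty and Eif2s3y carried it in both male and neither female library, and Kdm5d and Ddx3y in male replicate 1 only. Peaks within the first 3 Mb of chromosome Y, where these genes lie, numbered 6 and 2 in the male H3K27Ac lists and 0 in both female lists. Female lists did hold peaks beyond 90 Mb on Y: 4 for H3K27Ac and 6 for H3K4me1 in replicate 2, and 5 for Sp1. The male H3K4me1 replicate 1 list held 0 peaks on Y.

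The comparison of the sexes asked which chromatin was active in males or females only. For H3K27Ac, 2105 regions were called in both male and neither female library and 514 in both female and neither male library. The best-ranked male regions lay in Cacna2d3, a calcium channel subunit gene, in the chromatin remodelling genes Baz2a (2 regions) and Bptf, in the amino acid transporter gene Slc38a4, and at a distance from Bloc1s4, Oaf, Slc45a1, C1qtnf3 and Wdr75. The best female regions lay in Xist (nearest protein-coding gene Tsx), in Crtc3, Inf2, Nlgn1, Tjp3, Xdh, Mapre2 and the nuclear receptor gene Esrrb, 14378 bp from H4c8, and 385902 bp from Fgf9. For H3K4me1 the counts were 2764 and 2070. The best male regions included one inside Esr1, which encodes estrogen receptor alpha (chromosome 10, 4632544 to 4632995), others in Fam185a, Arhgef3, Aff1, Tcf7l2 and Arhgef28, and regions nearest to Bpgm, Zmiz1, Lhx2 and Kdm8. The best female regions lay in Gse1, Timp3, an inhibitor of matrix proteases, Rbms1, Tex21, Rbms3, Wipf1, Aknad1 and Trim62, and nearest to Ccdc130 and Prex1.

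At gene ends, 81 genes carried H3K27Ac in both male and neither female library and 21 the reverse. The best-ranked male genes were Nfil3, a circadian bZIP repressor, Car14, Uty, Rec8, Shroom2, 2310009B15Rik, Kbtbd6, Msi1, Spata31d1d and Tmem265, and the best-ranked female genes Xdh, Spata18, Gstt1, Ltb4r1, Plch1, S100a2, Tex52, Ltb, Spata32 and Nbeal1. Most were not strong calls. By the worse of the within-list rank percentiles, where low is best, Nfil3 stood at 8.97. The other male genes stood at 39.45 to 53.77 and the female genes at 41.07 to 85.19. Apart from the sex-linked genes, Col2a1, the collagen of cartilage, was the only member of the fixed lists marked in both libraries of one sex and neither of the other, and it was marked in males.

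The split by sex gave totals close to those of a split that mixes the sexes: 2619 against 2701 H3K27Ac regions, 4834 against 4455 H3K4me1 regions and 102 against 106 genes. Setting male replicate 1 and female replicate 2 against the other pair gave 351 and 2350 H3K27Ac regions, 2324 and 2131 H3K4me1 regions, and 17 and 89 genes. Setting replicate 1 against replicate 2 gave 17585 and 12026 H3K27Ac regions, 32912 and 26890 H3K4me1 regions, and 679 and 773 genes. The 3 possible splits of 4 libraries cannot give a p-value below 0.05, so none is given. At equal list length the male count for H3K27Ac was 777 and the female count 604, and 40 genes were male-only. With replicate 1 alone the excess of male H3K27Ac turned round, with 23758 male and 30514 female regions and 386 and 667 genes, whereas replicate 2 alone gave 37183 and 8331 regions and 1189 and 289 genes. For H3K4me1, replicate 1 alone gave 48698 and 47229 regions and replicate 2 alone 34841 and 30583.

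**Figure D4:**
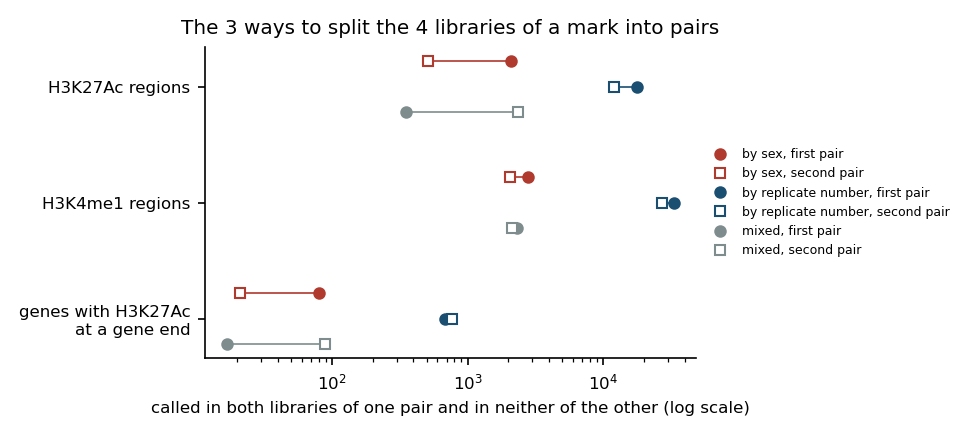
Number of H3K27Ac regions, H3K4me1 regions and genes with H3K27Ac at a gene end (x axis, log scale) called in both libraries of one pair and neither of the other, for the 3 splits of the 4 libraries of a mark; filled circles are the first pair (males, replicate 1, or male 1 with female 2) and open squares the other. The split by sex (2105 and 514 for H3K27Ac) lies near the mixed split, and the split by replicate number (17585 and 12026) far above both.

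Of the 2105 male H3K27Ac regions, 5 overlapped a shared AR region, against 0 of the 514 female regions (two-sided Fisher's exact test, p = 0.590). In the mixed split (male 1 with female 2, and the reverse), 0 of 351 and 1 of 2350 regions did. The 5 male regions were named after their values were seen. They lay in Zbtb16 (chromosome 9, 48724829 to 48725363), in Notch4 and in Tead1, a transcription factor of the Hippo pathway. The rest lay 58148 bp from Kcng1 and 113762 bp from Usp24. The Zbtb16 region met its shared AR region (48725331 to 48726544) only at the edge. There the H3K27Ac peak of male replicate 2 reached the AR region and that of male replicate 1 did not. For H3K4me1, 8 of 2764 male and 2 of 2070 female regions overlapped one (Fisher's exact test, p = 0.204), and the 2 female regions lay in Meis1 and 82054 bp from Cpm. In the mixed split of H3K4me1, 4 of 2324 and 1 of 2131 did. For the Sp1 regions of both sexes the counts were 69 and 25 for H3K27Ac (Fisher's exact test, p = 0.0863) and 139 and 90 for H3K4me1 (Fisher's exact test, p = 0.275). With replicate 1 alone, male-only regions held AR more often than female-only regions (odds ratio 3.45 for H3K27Ac, p = 6.85e-05, and 2.28 for H3K4me1, p = 1.86e-05, Fisher's exact tests). With replicate 2 alone the odds ratios were 1.87 (Fisher's exact test, p = 0.223) and 1.08 (Fisher's exact test, p = 0.745), and in the better-scoring 50% of each list the odds ratios were 0.539 (Fisher's exact test, p = 0.565) and 0.761 (Fisher's exact test, p = 1), so no direction was established there. At Sp1 the H3K27Ac odds ratio was 0.865 with replicate 1 alone (Fisher's exact test, p = 0.0127) and 0.918 with replicate 2 alone (Fisher's exact test, p = 0.160). That of H3K4me1 was 1.79 with replicate 1 alone (Fisher's exact test, p = 5.08e-79). With replicate 2 alone it was 0.784 (Fisher's exact test, p = 9.62e-10). With the replicate number as a block, chosen after seeing the data, all 4 odds ratios newly passed the threshold. At AR the odds ratios were 2.975 for H3K27Ac (exact conditional test, p = 3.46e-05) and 1.654 for H3K4me1 (exact conditional test, p = 5.41e-04). At Sp1 they were 0.8905 (exact conditional test, p = 0.00588) and 1.311 (exact conditional test, p = 3.45e-29). The pooled H3K4me1 value at Sp1 joins opposite directions, 1.79 and 0.784 in the single replicates, so it describes neither replicate. The block needs a difference in 1 pair of libraries in place of both, so many more regions enter.

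Counted per replicate, shared AR regions carried H3K27Ac more often in males than in females. In replicate 1 the shares were 88.5% in the male and 85.9% in the female, with 30 regions marked in the male list only and 14 in the female list only (exact McNemar test, adjusted p = 0.0302). In replicate 2 they were 77.7% and 70.7%, with 51 and 8 regions (exact McNemar test, adjusted p = 3.62e-08), but there the male list was also longer (75910 against 46292 peaks), and Sp1 regions differed in the same direction (87.7% and 81.7%). In replicate 1 the Sp1 regions differed the other way (66.3% and 67.6%). For H3K4me1 the shares were 70.9% and 63.8% in replicate 1 (exact McNemar test, adjusted p = 1.08e-04), where Sp1 regions again differed alike (51.1% and 44.2%), and 56.3% and 53.9% in replicate 2 (exact McNemar test, adjusted p = 0.184). These 4 tests were added after seeing the data, and they count regions, not animals. At Fkbp5, H3K27Ac was called at all 5 shared AR regions in male and female replicate 1, at 4 of 5 in male replicate 2 and at 1 of 5 in female replicate 2. At Isl1, Tbx3, Ptch1, Per1 and Mafb every shared AR region carried it in all 4 libraries. At Zbtb16 the region from 48725331 to 48726544 carried it in male replicate 2 only, and the others in all 4 libraries or in none.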

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

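The test of strong Sp1 peaks among H3K4me1 peaks was chosen after the result was seen, as was the grouping of Sp1 regions by rank. The test of the weaker H3K27Ac peaks on X replaced a test on the whole list after the whole-list share had been seen, and the sex counts at equal list length were known before the test of list length. Mitochondrial DNA entered no comparison, and the male Sp1 list held 6 peaks there, above the 3 that a count of 0 allows. The female Sp1 list held 2, and the other 10 lists 0. The strongest male peak (positions 15901 to 16299) had a fold enrichment of 3.37 and ranked in the best 19.8% of its list.

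Shared AR regions lay in chromatin with H3K27Ac and Sp1. Recovery of open chromatin whatever the antibody as the source of this overlap stays open. The 1000 best Sp1 regions held a shared AR region in 2.20% of cases and the others in 1.78% (odds ratio 1.26, Fisher's exact test, p = 0.327), although over 5 equal groups of Sp1 regions the share went from 3.10% in the best to 0.597% in the weakest. A biological explanation, recruitment of AR to such chromatin, was not tested.

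Replicate number separated the histone-mark lists far more than sex did. Unequal list length is not the whole cause, since at equal length 19590 H3K27Ac regions followed replicate number and 1381 followed sex, 14.2 times as many. The least peak width did not account for the difference among the best peaks. Of the 1000 best male H3K4me1 replicate 1 peaks of 300 bp or more, 14.6% lay near a gene end (14.1% without the width limit). Of the best 1000 of replicate 2, 75.1% did. The regions that followed replicate number were not recounted without the shorter peaks, so over whole lists the least width stays open. A candidate explanation is that strong chromatin at gene ends was recovered with both histone-mark antibodies in replicate 2, as in the Sp1 libraries. Of the 2000 best male Sp1 peaks, 42.2% were among the 2000 best male H3K4me1 peaks of replicate 2. For replicate 1 the share was 1.45%, and the ratio was 29.1. For H3K27Ac the shares were 68.3% and 15.7%. Position sets the replicates apart for H3K4me1 only. The best 1000 H3K27Ac peaks lay near a gene end about as often in replicate 1 (82.5% male, 79.9% female) as in replicate 2 (84.3% and 84.1%). Recovery at gene ends in replicate 2 alone therefore does not account for the H3K27Ac split. The mark lists of the replicates also differ in layout, and the platform of each library is not given in the sources used here, so replicate number, platform and peak calling cannot be told apart, and no biological explanation was tested.

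Few AR peaks lay on chromosome X, 21 of 9317 in replicate 1 and 8 of 3573 in replicate 2, with 0 among the 618 shared regions. Less H3K27Ac on X does not account for it, because within male H3K27Ac regions 3.15% of 444 on X and 14.4% of 25694 on the autosomes overlapped an AR peak (odds ratio 0.200, Fisher's exact test, p = 4.80e-15). The single X of males is not the whole cause, since even the weaker 50% of the male H3K27Ac replicate 1 list had 0.718% of its peaks on X, 3.18 times the AR share of 0.225% (Fisher's exact test, p = 2.95e-09). That weaker part lay below the 1.17% of the whole list, so the single copy may contribute. Female lists did not always have more of their peaks on X than male lists. For H3K27Ac the shares were 1.04% in the female and 1.17% in the male in replicate 1, and 1.22% and 1.08% in replicate 2. For H3K4me1 replicate 1 the female share of 0.186% lay below the AR share and the male share of 0.620%. In replicate 2 the H3K4me1 shares were close, and for Sp1 the female share was higher (1.81% against 1.21%). How X was treated in mapping or peak calling was not tested.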

How the results depend on the processing

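The exact McNemar tests, the replicate block, equal AR list length, the background and Hox alternatives, the extended gene span and female Sp1 were chosen after seeing the data. Of 147 alternatives over 24 results, 99 kept their direction and side of the threshold or stayed within the allowed range, 26 values moved, 7 fell short of the threshold, 12 newly passed it and 3 reversed. The overlap of shared AR regions with male H3K27Ac, H3K4me1 and Sp1 passed its test in every alternative run, but with a single AR list the share with H3K27Ac ranged from 31.8% to 52.1%. Shared AR regions numbered 241 with the better-scoring 50% of each list and 345 at equal list length. The share of male Sp1 peaks found in the female was 55.0% at equal length, 41.3% with 50% overlap and 58.4% for the better 50%.

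The H3K27Ac male-only count was 777 at equal length and 715 in the better 50%, and the female-only count 165 in the better 50%; a single replicate left 23758 to 37183 and 8331 to 30514. For H3K4me1 the better 50% gave 1314 and 1001, and single replicates 34841 to 48698 and 30583 to 47229. Genes with male-only H3K27Ac numbered 40 at equal length and 386 to 1189 with single replicates, and female-only genes 289 to 667. The male excess of H3K27Ac regions and genes turned round with replicate 1 alone; the cause was not tested. These single-replicate counts need 1 call and 1 missing call in place of 2, which raises them by construction. The odds ratio of male-only against female-only regions at AR fell below 1 in the better 50%, to 0.539 for H3K27Ac (Fisher's exact test, p = 0.565) and 0.761 for H3K4me1 (p = 1). The main values rest on 5 against 0 and 8 against 2 regions and did not pass either, so these 2 settings established neither direction. With single replicates it was 1.87 to 3.45 and 1.08 to 2.28, passing the threshold without replicate 2. The McNemar ratios were 2.14 and 6.38 for H3K27Ac and 2.22 for H3K4me1 in replicate 1. At Sp1 regions the H3K27Ac odds ratio was 0.544 at equal length and 0.865 to 0.918 with single replicates, past the threshold at equal length and without replicate 2; that of H3K4me1 ranged from 0.784, a reversal without replicate 1, to 1.79, so its direction followed the replicate. The cause was not tested.

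Gene lists with AR nearby numbered 2 to 7 with a single AR list, 2 without replicate 2. A 5 kb window put 57.1% of shared AR regions near a gene end, by construction, and with a gap of 5 kb the longest domain covered 108.6 kb, and 6 of the 10 longest lay in the main 10. The labels give the libraries of the sexes a shared number and no other tie; same-numbered lists of the sexes shared more of their bases (Jaccard 0.515 and 0.451 for H3K27Ac, 0.365 and 0.425 for H3K4me1) than lists of the sexes with different numbers (at most 0.269 and 0.142). With that number as a replicate block, the odds ratios at AR were 2.97 for H3K27Ac (p = 3.46e-05) and 1.65 for H3K4me1 (p = 5.41e-04), and those at Sp1 0.890 (p = 0.00588) and 1.31 (p = 3.45e-29) in exact conditional tests. All 4 newly passed the threshold; the block needs a difference in 1 pair of libraries in place of both, so many more regions enter, and a region can enter under both numbers. For H3K4me1 at Sp1 the replicates went in opposite directions (1.79 without replicate 2, 0.784 without replicate 1), so the pooled 1.31 describes neither. For the counts of sex-specific regions the block is the main definition. Motif alternatives were not run. Unknown depth limits every count of missing peaks: absence from a list is not absence of binding.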

Other observations

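The tests in this part were chosen after the results were seen. Shared AR regions came in groups. Of the 618, 124 (20.1%, 95% Wilson interval 17.1 to 23.4) lay within 10 kb of another, against a mean of 4.10% and a maximum of 8.25% in 1000 random draws of as many male H3K27Ac regions (one-sided permutation p = 0.001, the smallest these draws can give). Several AR regions can lie in a single H3K27Ac region, which such draws cannot match. AR regions were not joined across gaps, so adjoining calls, such as those in Zbtb16 from 48736778 to 48740648, also count as a group. With each H3K27Ac region counted once, 11.8% (interval 9.13 to 15.2) of the 440 that held AR lay within 10 kb of another, against a mean of 2.82% and a maximum of 6.59% in random draws of 440 (permutation p = 0.001, the smallest these draws can give). After Zbtb16 with 8, the genes with most shared AR regions inside them were Meis1, a TALE homeobox gene, Nfix, a nuclear factor I gene, and Gse1, with 4 each, followed with 3 each by the T-box genes Tbx3 and Tbx5, the odd-skipped gene Osr2, Zmynd8 and Arhgap28. Osr2 spans 7.21 kb and Tbx3 14.2 kb, so the count does not simply follow gene length.

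H3K4me1 peaks on chromosome X made up 0.620% of the list in male replicate 1 and 0.186% in female replicate 1, but 0.740% and 0.724% in replicate 2. For Sp1 the shares were 1.21% in the male and 1.81% in the female.

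One hypothesis was that shared AR regions carry a mark in males and not in females more often than Sp1 regions without AR do. The AR regions were selected in male libraries and the Sp1 regions in both sexes, so the peaks of the male Sp1 list without AR were used as a second comparison. For H3K27Ac in replicate 1 the male-only and female-only counts were 30 and 14 at AR regions and 462 and 691 at Sp1 regions (odds ratio 3.14, Fisher's exact test, adjusted p = 0.00105 over 4 tests). In replicate 2 they were 51 and 8 against 1391 and 334 (odds ratio 1.46, Fisher's exact test, adjusted p = 0.420). For H3K4me1 the odds ratios were 1.16 in replicate 1 (Fisher's exact test, adjusted p = 0.488) and 1.48 in replicate 2 (Fisher's exact test, adjusted p = 0.101). Against the male Sp1 peaks the odds ratios were 2.88 for H3K27Ac in replicate 1 (Fisher's exact test, adjusted p = 0.00257) and 1.02 in replicate 2 (adjusted p = 1), and 1.28 and 0.883 for H3K4me1 (adjusted p = 0.487 and 0.745). Male-biased H3K27Ac at AR regions may exist, but it passed in replicate 1 only, where it rests on 1 male and 1 female library, and selection of the AR regions in males stays open. Regions called in AR replicate 2 only went the same way in H3K27Ac replicate 1 (64.0% in the male, 58.6% in the female), and regions called in AR replicate 1 only did not (36.9% and 37.8%).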
